A study of Mus musculus with 9 samples.

How the data were processed

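Lung macrophages of 9 female wild-type mice, 3 after air and 3 each at 24 h and 72 h after ozone, were profiled by RNA sequencing. Per the labels' protocols, red cells were lysed before RNA extraction, RNA integrity numbers were at least 8.8, and libraries were made with a stranded total RNA kit. The deposited values are estimated counts per gene, summed over transcripts and not scaled to library size; 80.5% of them are whole numbers. Per the submitters' processing notes, reads were processed with Trimmomatic 0.39, FastQC, Salmon and DESeq2 on the GRCm38.p6 build; the other versions, the annotation release and the options are not given in the sources used here. A last unnamed column of the table holds 3 gene symbols and no measurement, and was not used here. Identifiers are Ensembl genes with versions; symbols and coordinates come from GENCODE M21, which matched 54107 of 54281 identifiers (53544 with the version) and left 174 without a symbol. Whether strand was used in counting is not given in the sources used here, so overlapping antisense genes and genes with near-identical copies are uncertain.

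The estimated counts were rounded to whole numbers and analysed in R 4.3.3. Genes with too few counts were removed by filterByExpr of edgeR 4.0.16, which kept 15713 genes. Libraries were scaled by TMM, and all 9 libraries entered 1 quasi-likelihood fit with robust dispersion, so that the 3 groups shared their estimate of spread; the common biological coefficient of variation was 0.312. The contrasts were 24 h against air, 72 h against air and 72 h against 24 h, with a joint F test for any difference. P-values were adjusted by Benjamini and Hochberg over all genes tested, and genes with an adjusted p under 0.05 are referred to as called. SE was taken as the log2 fold change divided by the square root of F. Totals per library were 47095543 to 60248305 counts. DESeq2 left 3415, 402 and 1618 genes without an adjusted p in the 3 contrasts.

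The gene lists, 31 in number, were fixed before the data were examined, as were the comparisons, tests, rule for named genes and most of the alternatives. They comprise 19 functional and 12 cell type lists, and 30 had at least 5 tested members. They were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, and again with an estimated correlation and with fry, whose directional p asks whether the genes of a list move one way on balance without comparing them with other genes. No camera call held with an estimated correlation. For each list the counts of genes called over all genes and adjusted over the list alone are given. Further lists (serous cavity macrophage, thymocyte, alveolar type 1 and type 2 cell, airway epithelium, Y-linked genes and X genes that escape inactivation) were written after the data were seen.

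Genes are named by this rule. In each contrast, the rule takes the 10 called genes with the largest change in each direction that average at least 5 CPM in the higher group, with all 3 libraries of one group above those of the other and a symbol that is not a clone or pseudogene name. From each list it takes up to 4 called members with the smallest p or, where none is called, the 2 with the highest level. A roster of 22 genes is given whatever the result. Epcam and Cdh1 stand as the most abundant lung epithelium markers. Genes named outside the rule were chosen after their values were seen, and are said to be. Single values of a few genes are not reported here.

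The procedure was tested on simulated data drawn from the means and library sizes of the real genes, with changes of 1.5-fold, 2-fold and 4-fold in 67, 67 and 66 genes. Each gene was drawn independently, with the spread typical of its level. The rates therefore do not cover correlated genes or libraries that carry markers of other cells. For 24 h against air 29.9%, 49.3% and 69.7% of them were recovered, for 72 h against air 17.9%, 44.8% and 71.2%, and for 72 h against 24 h 14.9%, 35.8% and 66.7%, with 5 of 104, 9 of 98 and 1 of 79 calls false. An exact permutation test of 3 against 3 mice cannot go below p = 0.1, two-sided. Libraries of a group were checked for duplicates, and none was a copy of another (chi-square per degree of freedom 6.82 to 128).

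Alternatives were other scalings (DESeq2 size factors, upper quartile), other filters (none, or 1 CPM in 3 libraries), the replicate number as a block, DESeq2 1.42.0, limma voom, only the 6 libraries compared, a 2-fold threshold, removal of mitochondrial, ribosomal RNA and the 10 most abundant genes, and each library left out in turn. Added after the data were seen were fits without the 2 libraries carrying serous cavity markers, without these and the air library lacking Xist, and with the serous cavity level as a covariate. Correlated changes against the shared air libraries were compared with 100 simulations of unchanged groups. Other splits of the libraries into groups of the same sizes were counted.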

Results

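Gene expression was measured by total RNA sequencing in lung macrophages of female wild-type mice aged 12 weeks. The cells were collected by bronchoalveolar lavage with massage of the lung. Of 9 mice, 3 had breathed air, 3 were killed 24 h after a 3 h exposure to ozone at 0.8 ppm, and 3 were killed 72 h after it, so that each of the 3 groups holds n = 3 separate mice. Ozone is an oxidant air pollutant that injures the lining of the airways and alveoli. The deposited values were estimated counts per gene, with totals of 51797737, 60248305 and 60171106 counts in air, 50826921, 47095543 and 47693586 at 24 h, and 49330729, 53630150 and 48882768 at 72 h. Of 54281 genes, 15713 were tested, and levels below are CPM, counts scaled to library size, as mean ± SD with n = 3. Changes are log2 fold changes ± SE from edgeR, a called gene had an adjusted p under 0.05, and coordinates are on GRCm38.

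Markers of resident alveolar macrophages, the self-renewing macrophages of the air spaces, stood above those of 11 other cell types in air. The summed level of 20 marker genes, among them Siglecf, Ear1 and Krt79, was 16505 ± 191 CPM in air. A pair of ozone libraries also carried markers of other cells. Summed B cell markers reached 1807 CPM in replicate 2 at 24 h and 1013 CPM in replicate 1 at 72 h, against 3.45 to 14.9 CPM in the other 7. T cell markers reached 1325 and 301 CPM there, against 233 to 262 CPM. Markers of the large macrophages of serous cavities, such as Prg4 and Alox15, a list and genes chosen after the values were seen, summed to 784 and 1019 CPM, against 4.45 to 8.61 CPM. Mitochondrially encoded genes took 5.25% and 6.18% of the counts in these 2 libraries and 2.71% to 3.07% in the other 7. Red cell markers were 2942 and 2547 CPM in them, 874 CPM in replicate 1 at 24 h, and 22.8 to 154 CPM in the other 6. The first principal component, 54.2% of the variance of log2 CPM, placed these 2 libraries at 104 and 80.4 and the other 7 between -45.7 and -0.459. The number of called genes in each comparison is therefore also given without these 2 libraries, a choice made after the data were seen.

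**Figure D1:**
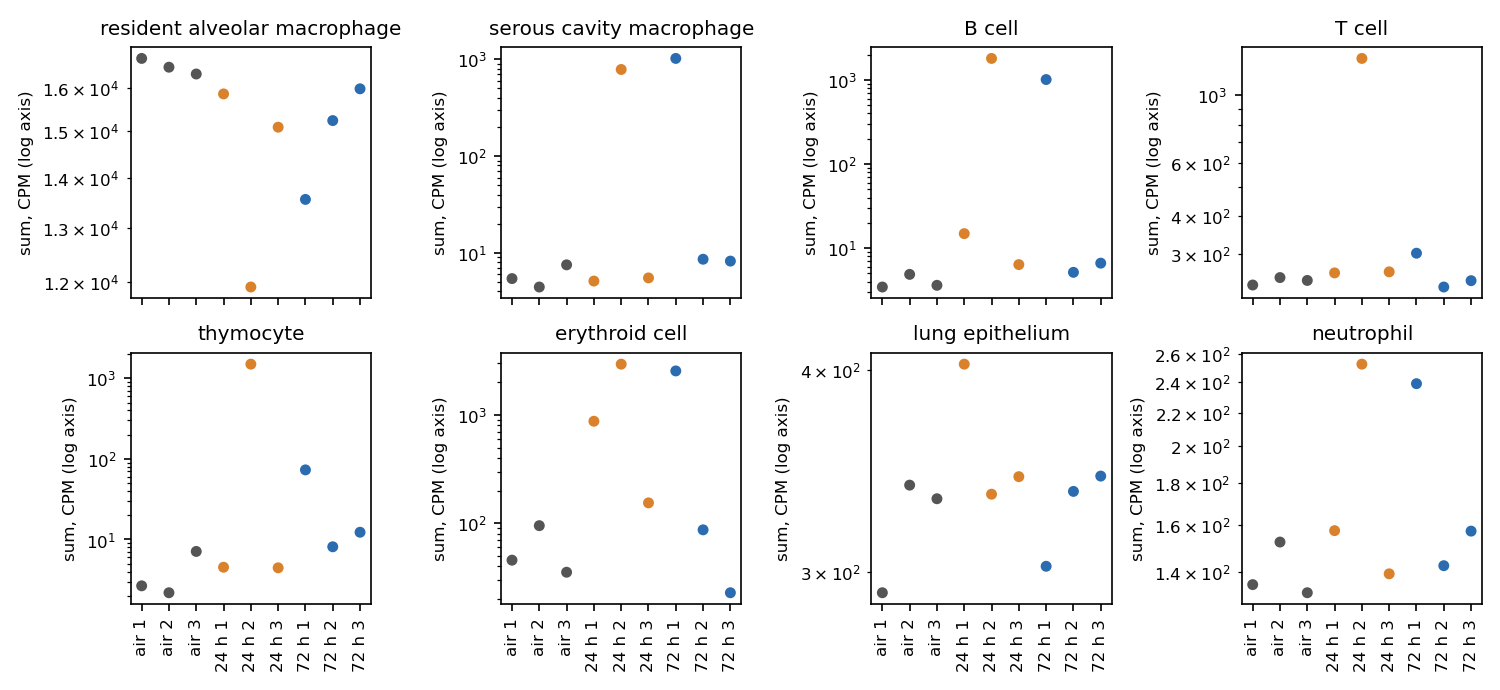
Summed CPM (log axis) of marker genes of 8 cell types in each of the 9 libraries; each point is 1 library, grey for air, orange for 24 h and blue for 72 h. Replicate 2 at 24 h and replicate 1 at 72 h hold the most serous cavity macrophage and B cell transcripts and the least of the resident alveolar macrophage markers, 11917 and 13563 CPM.

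The first comparison asked what differed in the macrophages 24 h after ozone. Genes of DNA replication stood higher at 24 h than in air as a group. All 21 of 21 members of the list for DNA replication and S phase had a positive log2 fold change, with a median of 0.56. Mcm6, a subunit of the replicative helicase, was 102 ± 15.3 CPM in air and 159 ± 11.9 CPM at 24 h (0.64 ± 0.12), and Pcna, the sliding clamp of DNA polymerase, was 253 ± 23.2 and 329.7 ± 21.6 CPM (0.38 ± 0.09). None of the 21 was called by edgeR over all genes, and 21 were higher when adjusted over the list alone. The list was called higher by limma's camera, adjusted p = 1.67e-19, but not with an estimated correlation, adjusted p = 0.631. Limma's fry gave adjusted p = 0.0362, and 0.150 without the 2 libraries. Of 22 genes of G2 and mitosis, 21 were higher adjusted over the list alone and 0 over all genes, with a median log2 fold change of 0.48. Camera gave adjusted p = 9.52e-15 and adjusted p = 0.631 with an estimated correlation, and fry 0.0643. Top2a, which untangles DNA before division, was 131 ± 20.7 CPM in air and 196 ± 5.63 CPM at 24 h, and the proliferation marker Mki67 was 206 ± 20.2 and 281 ± 23.2 CPM. With the 2 libraries left out the medians were 0.55 and 0.51, with camera adjusted p = 2.87e-15 and 1.07e-13.

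For cholesterol biosynthesis the fold changes at 24 h also pointed upward, but only camera with the preset correlation called the list. All 20 tested members had a positive log2 fold change, 14 were higher adjusted over the list alone and 0 over all genes, and the median was 0.40. Hmgcs1, an early enzyme of the pathway, was 182 ± 22.8 CPM in air and 221 ± 32.9 CPM at 24 h. Camera gave adjusted p = 9.82e-10, adjusted p = 0.631 with an estimated correlation, and fry 0.179. Relative to air the median of these genes was 0.53, 0.19 and 0.53 in replicates 1, 2 and 3 at 24 h, lowest in the library with lymphocyte markers, and without the 2 libraries the median was 0.51 with adjusted p = 5.14e-14. The calls of the DNA replication, G2 and mitosis and cholesterol lists held with each of the 9 libraries left out in turn.

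Single genes passed the test rarely at 24 h. The only one called was H1f0, the linker histone H1.0 found mainly in cells that have left the cell cycle (ENSMUSG00000096210.2, chromosome 15, 79028450 to 79030504). It fell from 34.8 ± 0.978 to 23.7 ± 0.481 CPM, a log2 fold change of -0.55 ± 0.05 with edgeR adjusted p = 0.0225. With 1 library left out, it was called only without replicate 2 at 24 h, and its adjusted p was at most 0.182 over the 9 such fits. The macrophage marker Siglecf was 471 ± 49.8 CPM in air and 314 ± 75.4 CPM at 24 h (-0.59 ± 0.17, adjusted p = 0.209), and the scavenger receptor Cd36 479.8 ± 74.9 and 328 ± 59.8 CPM (-0.55 ± 0.16, adjusted p = 0.212). Spp1, which encodes osteopontin, was 303 ± 11.3 and 457 ± 54.2 CPM (0.59 ± 0.13, adjusted p = 0.120; without the 2 libraries 0.69, adjusted p = 0.0237). Heme oxygenase Hmox1 was 216 ± 6.27 and 159 ± 14.3 CPM (-0.45 ± 0.12, adjusted p = 0.176). The cytokine genes Il1b and Tnf were 11.9 ± 5.06 and 13.3 ± 9.34 CPM in air against 18.5 ± 0.857 and 9.69 ± 2.91 CPM at 24 h, neither called. Nos2 had at most 3 counts in any library and was not tested. Arg1 was high only in air replicate 3, at 26.4 CPM against 0.236 to 5.08 CPM in the other 8 libraries.

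Camera called 18 of 30 lists at 24 h, 13 higher and 5 lower. With an estimated correlation it called 0, with 2 at an unadjusted p under 0.05, and fry called 2. Camera called 8 lists without replicate 2 at 24 h and 11 without both libraries carrying B cell markers, where fry called 0 and, with an estimated correlation, 0 lay at an unadjusted p under 0.05. Resident alveolar macrophage markers lay lower, with a median log2 fold change of -0.22 over 20 genes, 4 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.0003 and adjusted p = 0.631 with an estimated correlation. When the 2 libraries in which these markers were lowest were left out, the median was -0.11 and adjusted p = 0.00791. Glycolysis (median log2 fold change 0.15, adjusted p = 0.0104) and oxidative phosphorylation (0.07, adjusted p = 0.00483) lay higher and fatty acid oxidation (-0.12, adjusted p = 0.00308) lower, each with adjusted p = 0.631 with an estimated correlation. Of these 1 glycolysis gene was higher and 0 genes of the other lists were called adjusted over the list alone. The glycolysis call ended without air replicate 1 (adjusted p = 0.0510) or replicate 1 at 24 h (0.0760), that of oxidative phosphorylation without air replicate 1 (0.0589), and that of fatty acid oxidation without replicate 2 at 24 h (0.0542).

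Markers of other cells were also called at 24 h. B cell (7.55), T cell (5.22), neutrophil (1.99) and erythroid (4.80) markers were called higher, with adjusted p = 0.00308, 0.00351, 0.00878 and 0.00308, and all at adjusted p = 0.631 with an estimated correlation. Their medians without the 2 libraries were 2.02, 0.04, 0.82 and 3.35, with adjusted p = 2.81e-08, 0.457, 0.00192 and 0.000345. Without replicate 2 at 24 h alone, the B cell, T cell and neutrophil calls ended, at adjusted p = 0.168, 0.682 and 0.0654, and the neutrophil call ended also without air replicate 3, at 0.0522. Lung epithelium markers had a median of 0.23 (adjusted p = 0.0163, and adjusted p = 0.631 with an estimated correlation). Without the 2 libraries it was 0.30, with adjusted p = 0.00351. The epithelial call was lost without air replicate 1 (0.198) or replicate 1 at 24 h (0.0506).

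Interferon response (0.30), MHC class II (0.46) and p53 targets (0.20) were called higher, and lipid handling (-0.27), NRF2 targets (-0.08) and lysosome (-0.07) lower, with camera adjusted p = 0.0163, 0.0359, 0.0163, 0.00166, 0.0105 and 0.0465. With an estimated correlation the adjusted p was 0.631 for each of these but lysosome, where it was 0.747. Adjusted over the list alone, 1 interferon gene was higher, 1 NRF2 target was higher and 2 were lower. None of these 6 calls remained without the 2 libraries, at adjusted p = 0.571, 0.965, 0.113, 0.0604, 0.0565 and 0.987. The medians were then 0.03, 0.04, 0.11, -0.17, -0.07 and 0.01, so that the lysosome median changed sign while NRF2 targets and lipid handling kept most of their size. Without replicate 2 at 24 h alone the adjusted p values were 0.504, 0.682, 0.0654, 0.0654, 0.111 and 0.978. The interferon call also ended without air replicate 1 (0.0631) or 2 (0.141), MHC class II without air replicate 1 (0.164) or 3 (0.0530) or replicate 1 at 24 h (0.0577), p53 targets without air replicate 3 (0.0522), NRF2 targets without replicate 3 at 24 h (0.0713), and lysosome without air replicate 1 (0.0501) or 3 (0.152) or replicate 2 at 72 h (0.0539).

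Not called at 24 h were the tricarboxylic acid cycle (median 0.04, camera adjusted p = 0.195), pro-inflammatory mediators (-0.07, 0.914), alternative activation (0.02, 0.881), tissue repair (-0.02, 0.833), pattern recognition receptors (-0.07, 0.0895), unfolded protein response (-0.04, 0.833), iron handling (-0.0013, 0.941), monocytes (1.47, 0.217), interstitial macrophages (1.92, 0.195), natural killer cells (4.11, 0.160), dendritic cells (0.26, 0.229) and endothelium with fibroblasts (4.30, 0.399). The medians of the last 5 were, without the 2 libraries, -0.11, -0.09, -0.11, 0.01 and -0.17. The list of eosinophil, basophil and mast cell genes had 1 tested member, Hdc, and was not tested. Median, mean and camera direction differed in sign for pro-inflammatory mediators (mean 0.21, direction down), alternative activation (0.50, down), tissue repair (0.26, up), pattern recognition receptors (0.14, down), unfolded protein response (-0.03, up) and iron handling (0.40, down).

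In all, edgeR called 1 gene at 24 h. An unadjusted p under 0.05 was reached by 2314 genes, where a share of 0.05 of the genes tested is 786. Genes that move together can shift this number without an effect, and other splits were counted by called genes only. Voom called 1 gene and DESeq2 618 (422 higher and 196 lower). Without the 2 libraries 24 genes were called, 16 higher and 8 lower, with H1f0 among them. By list, 1 glycolysis, 1 cholesterol, 1 repair, 1 interferon and 1 neutrophil gene were then higher and 1 NRF2 target lower. Leaving out also the air library that lacked Xist, air replicate 2, 1 gene was called, and it was not H1f0. Leaving out 1 library at a time gave 0 calls, except 2 without replicate 2 at 24 h.

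**Figure D2:**
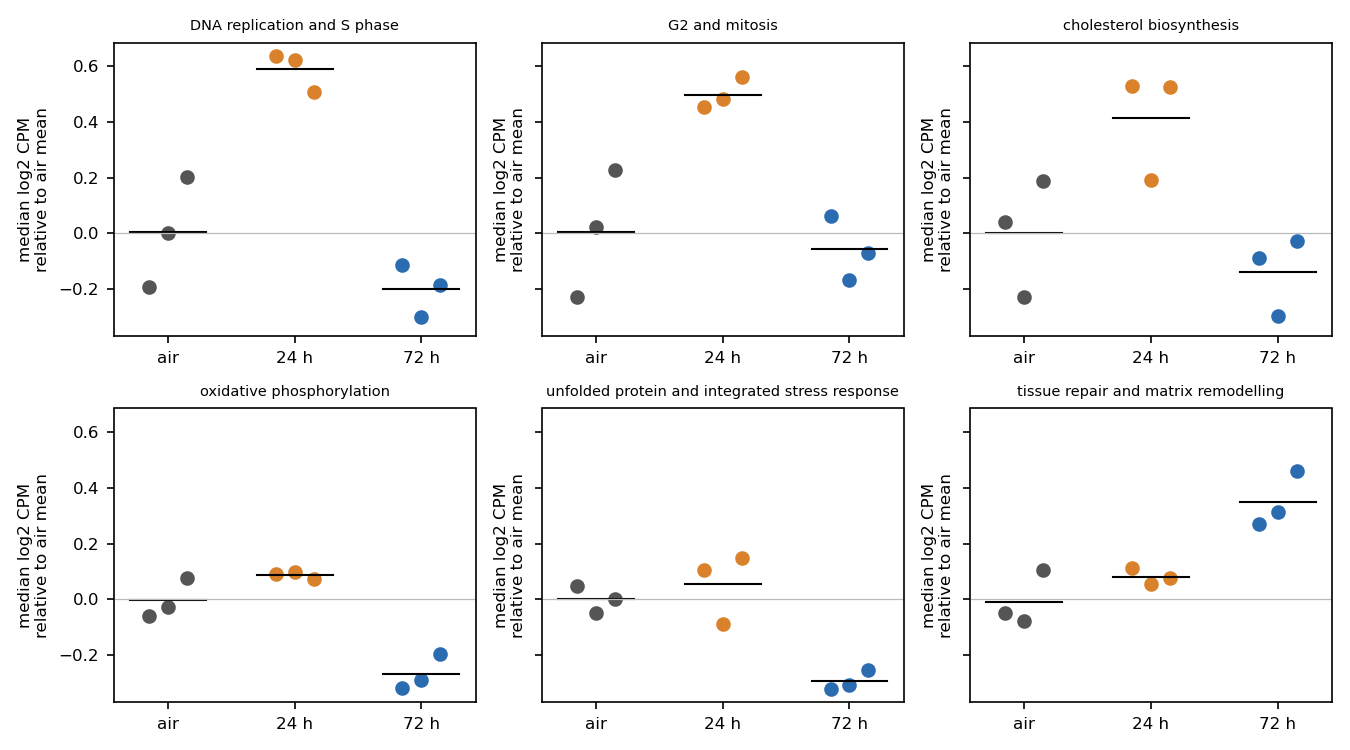
Median over the genes of 6 lists of log2 CPM relative to the mean of the air libraries, for each group; each point is 1 library and the line is the mean of 3. DNA replication genes lie between 0.51 and 0.64 at 24 h and between -0.30 and -0.12 at 72 h.

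The second comparison asked what differed from air 72 h after ozone. Of 18 lung epithelium markers, 6 rose, from low levels. Cldn18, a tight junction protein of alveolar epithelium (ENSMUSG00000032473.13, chromosome 9, 99689461 to 99717267), rose from 0.839 ± 0.232 to 11.5 ± 3.40 CPM, a log2 fold change of 3.77 ± 0.36 with edgeR adjusted p = 0.00421. The keratins Krt8 and Krt18 reached 6.55 ± 1.31 and 5.17 ± 1.32 CPM from 0.664 ± 0.119 and 0.525 ± 0.0372 CPM (3.30 ± 0.51 and 3.29 ± 0.39). Of genes outside that list, Emp2 reached 8.63 ± 2.16 from 1.19 ± 0.0530 CPM (2.85 ± 0.22), and Gprc5a 5.41 ± 1.10 from 0.661 ± 0.0625 CPM (3.03 ± 0.21). Of the epithelial list 0 genes were lower and 12 not called (7 higher and 1 lower without the 2 libraries), with 7 higher adjusted over the list alone. With each library left out in turn, Cldn18, Emp2 and Gprc5a were called in 9 of 9 fits, Krt18 and Ager in 7, Aqp5 in 5 and Krt8 in 3. Ager, a marker of alveolar type 1 cells, was 1.12 ± 0.279 CPM in air and 4.24 ± 0.692 CPM at 72 h, and the water channel Aqp5 0.425 ± 0.233 and 2.55 ± 0.424 CPM. Camera gave the list adjusted p = 0.000132, adjusted p = 0.314 with an estimated correlation, and fry 0.00686. The summed level of all its genes was 321 ± 26.1 CPM in air and 328 ± 22.1 CPM at 72 h, since Epcam (104 ± 7.36 and 97.2 ± 19.7 CPM) and Cdh1 (106 ± 24.0 and 102 ± 3.76 CPM) were high throughout and not called.

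Of 22 matrix and repair genes, 5 rose and 17 were not called. Fn1, which encodes fibronectin (ENSMUSG00000026193.15, chromosome 1, 71585520 to 71653200), rose from 1655 ± 281 to 3571 ± 741 CPM (1.11 ± 0.20, adjusted p = 0.0280). The collagenases Mmp8 and Mmp14 rose by 0.80 ± 0.16 and 1.30 ± 0.30, and the growth factor Hbegf, at 0.0744 ± 0.0511 CPM in air, by 2.38 ± 0.55. In the repair list 10 were higher and 1 lower adjusted over the list alone; camera gave adjusted p = 0.000115, adjusted p = 0.314 with an estimated correlation, and fry 0.00732. Of 14 dendritic cell genes, 4 were higher and 10 not called, with 7 higher and 1 lower adjusted over the list alone. Itgae, which encodes CD103, (ENSMUSG00000005947.11, chromosome 11, 73090583 to 73147446) rose from 7.005 ± 1.24 to 16.1 ± 2.51 CPM (1.20 ± 0.18), the cytokine receptor Flt3 by 1.52 ± 0.30, the transcription factor Zbtb46 by 0.98 ± 0.19, and Fscn1 by 1.48 ± 0.30. Camera gave adjusted p = 0.000115, adjusted p = 0.426 with an estimated correlation, and fry 0.0190. These 3 lists were called higher also without the 2 libraries, with medians of 1.17 for dendritic cell, 0.35 for repair and 0.74 for epithelial genes and camera adjusted p = 5.42e-05, 1.95e-05 and 0.000939; 9 dendritic cell and 10 repair genes were then higher. Clu (clusterin) stood at 13.6 CPM already in replicate 2 at 24 h, and was 1.01 ± 0.288 CPM in air and 21.8 ± 3.36 CPM at 72 h (4.43 ± 0.92). With each library left out in turn, Itgae was called in 5 of 9 fits, Fn1 and Zbtb46 in 3, and Mmp8, Mmp14, Hbegf, Flt3, Fscn1 and Clu in 2.

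Some genes of mitochondrial energy metabolism fell at 72 h, and most members of each list did not pass the test. Of 23 oxidative phosphorylation genes, 8 were lower, 15 were not called, and 20 were lower adjusted over the list alone, with a median log2 fold change of -0.26. The complex I subunits Ndufa9 and Ndufv1 went from 64.2 ± 1.38 to 50.9 ± 3.08 CPM and from 87.1 ± 7.71 to 67.8 ± 1.60 CPM. Fatty acid oxidation had 6 of 18 genes lower (11 adjusted over the list alone), among them Acadvl (-0.37 ± 0.06) and Etfb (-0.44 ± 0.07), and the tricarboxylic acid cycle 2 of 16 (9 adjusted over the list alone), Mdh2 (-0.34 ± 0.08) and Idh3g (-0.20 ± 0.05). Camera gave adjusted p = 1.68e-09, 8.07e-06 and 8e-05, against adjusted p = 0.478, 0.557 and 0.557 with an estimated correlation and 0.0121, 0.0190 and 0.0181 by fry (0.0446, 0.0350 and 0.0776 without the 2 libraries). Left without the 2 libraries, the medians were -0.21, -0.15 and -0.12, and 3, 5 and 0 members were lower. With each library left out in turn, Ndufa9, Acadvl and Etfb were called in 4 of 9 fits, Ndufv1 in 3, Mdh2 in 2 and Idh3g in 0.

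Of the stress response genes 5 of 17, and of the NRF2 targets 4 of 21, fell at 72 h. Atf4, the transcription factor of the integrated stress response (ENSMUSG00000042406.8, chromosome 15, 80255184 to 80257541), fell from 125 ± 5.74 to 88.9 ± 1.14 CPM (-0.50 ± 0.05, adjusted p = 0.00480), and Asns, one of its targets, from 6.79 ± 1.04 to 3.41 ± 0.0587 CPM (-0.99 ± 0.16). Of 17 genes of the unfolded protein and integrated stress response, those lower included Manf and Creld2, 12 were not called and 10 were lower adjusted over the list alone. Atf5, another stress transcription factor, fell from 24.2 ± 5.26 to 10.9 ± 0.661 CPM (-1.16 ± 0.18). Of 21 NRF2 targets and antioxidant genes, 4 were lower, 17 not called and 10 lower adjusted over the list alone, among them Gpx4 (-0.44 ± 0.07), Mgst1 (-0.54 ± 0.11), Hmox1 (216 ± 6.27 to 144 ± 23.3 CPM, -0.59 ± 0.12) and Txn1 (-0.38 ± 0.08). Camera gave the 2 lists adjusted p = 5.58e-06 and 0.000119, adjusted p = 0.314 and 0.478 with an estimated correlation, and fry 0.00686 and 0.0190; without the 2 libraries 6 and 6 members were lower. The camera calls of the epithelial, repair, dendritic cell, stress, NRF2 and 3 energy lists held with each of the 9 libraries left out in turn. These fits kept the preset correlation of 0.01, where the estimates ran from 0.038 for repair to 0.566 for oxidative phosphorylation. Among genes Atf4 was called in 9 of 9 such fits, Manf in 5, Asns, Atf5 and Gpx4 in 4, and Creld2, Mgst1, Hmox1 and Txn1 in 2.

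Markers of resident alveolar macrophages were mixed. Fabp1, a fatty acid binding protein (ENSMUSG00000054422.7, chromosome 6, 71199827 to 71205023), fell from 177 ± 33.1 to 90.4 ± 8.62 CPM (-0.97 ± 0.13), Krt79 from 572 ± 42.1 to 351 ± 40.3 CPM (-0.70 ± 0.12) and Ear1 from 704 ± 87.9 to 434 ± 72.5 CPM (-0.70 ± 0.14). The other 17 of 20 were not called (4 lower and 1 higher without the 2 libraries), 5 were lower adjusted over the list alone, and the list's median was -0.11 with camera adjusted p = 0.275. Siglecf was 425 ± 40.0 CPM (-0.15 ± 0.17, adjusted p = 0.607) and Pparg, a transcription factor that alveolar macrophages need, 170.1 ± 15.5 CPM (-0.36 ± 0.09, adjusted p = 0.0508; without the 2 libraries -0.27, adjusted p = 0.0358). The scavenger receptor Marco fell from 478 ± 55.9 to 347 ± 28.5 CPM (-0.46 ± 0.10) as the single called gene of 25 pattern recognition receptors (3 higher and 1 lower without the 2 libraries). Chil3, the most abundant alternative activation gene, was 23710.0 ± 1328 CPM in air and 19800.0 ± 1694 CPM at 72 h, and Mrc1 was 2419 ± 186 and 2272 ± 263 CPM, neither called. In the 9 fits with a library left out, Fabp1 was called in 5, Krt79 in 3, and Ear1, Marco and Ptgs2 in 2. Ptgs2, the inducible cyclooxygenase, rose to 0.667 ± 0.152 CPM (2.71 ± 0.55) as the single called pro-inflammatory gene (3 without the 2 libraries), with 17.0 ± 5.85 CPM of Il1b and 7.05 ± 1.40 CPM of Tnf. The monocyte receptor Ccr2 was 19.6 ± 3.73 CPM in air and 40.8 ± 12.3 CPM at 72 h (1.06 ± 0.45, adjusted p = 0.195; without the 2 libraries 0.81, adjusted p = 0.0427).

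Camera called 15 of 30 lists at 72 h, 9 higher and 6 lower; with an estimated correlation it called 0, with 3 at an unadjusted p under 0.05, and fry called 8. Camera called 9 without replicate 1 at 72 h, and fry 12 without the 2 libraries. DNA replication genes were lower (median -0.23, adjusted p = 0.0115, and adjusted p = 0.752 with an estimated correlation), with Pcna falling from 253 ± 23.2 to 195 ± 10.5 CPM as the single called member and the single one adjusted over the list alone. That list's call ended without air replicate 3 (adjusted p = 0.253) or replicate 2 at 72 h (0.0995). Pcna itself was called in 1 of the 9 fits with a library left out. Markers of monocytes (1.27), interstitial macrophages (2.27), neutrophils (1.49), T cells (2.44), B cells (7.09) and endothelium with fibroblasts (3.46) were higher, with camera adjusted p = 0.0225, 0.00591, 0.0103, 0.0430, 0.0284 and 0.0181 and adjusted p = 0.679, 0.665, 0.665, 0.752, 0.752 and 0.624 with an estimated correlation. Called members were Ace (0.58 ± 0.09) of the monocyte and Cxcr2 (5.84 ± 0.426 to 13.9 ± 1.81 CPM, 1.25 ± 0.12) of the neutrophil list; adjusted over the list alone 2 monocyte and 1 neutrophil genes were higher. Without replicate 1 at 72 h, which carried B cell and serous cavity transcripts, these 6 calls ended, at adjusted p = 0.107, 0.0532, 0.107, 0.241, 0.625 and 0.0532. The T cell call ended also without air replicate 1 (0.102) or 2 (0.108) or replicate 1 at 24 h (0.0607), the B cell call without air replicate 1 (0.0558) or 3 (0.0526) or replicate 1 at 24 h (0.0618), and the monocyte call without replicate 1 at 24 h (0.0512). With both libraries carrying B cell markers left out, the medians were 0.48, 0.56, 0.38, 0.91, 0.14 and 1.91, so that most of their size rested on replicate 1 at 72 h except for endothelium with fibroblasts. In these lists 4, 3, 3, 1, 0 and 4 genes were then higher. Adjusted p was then 0.00840, 6.24e-05, 0.0495, 0.00177, 0.460 and 0.0005.

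Not called at 72 h were G2 and mitosis (median -0.07, camera adjusted p = 0.929), glycolysis (-0.14, 0.106, with Tpi1 at -0.38 ± 0.06 and Ldha at -0.33 ± 0.08 lower and 5 lower adjusted over the list alone), cholesterol biosynthesis (-0.15, 0.0849, but -0.17 and 0.0144 without the 2 libraries), lipid handling (-0.08, 0.578), pro-inflammatory mediators (0.12, 0.684), alternative activation (-0.09, 0.629), interferon response (0.10, 0.216), MHC class II (0.51, 0.0814), pattern recognition receptors (0.08, 0.565), p53 targets (0.09, 0.212, with Zmat3 higher by 0.29 ± 0.07), iron handling (0.0075, 0.465), lysosome (-0.000625, 0.973), natural killer cells (2.96, 0.197) and erythroid cells (4.17, 0.109). The medians of the last 2 were, without the 2 libraries, 0.62 and -0.04. In the 9 fits with a library left out, Tpi1 was called in 4, and Ldha and Zmat3 in 1. Median, mean and camera direction differed in sign for lipid handling (mean 0.07, direction down), alternative activation (0.36, up), iron handling (0.20, down) and lysosome (mean -0.0143, up).

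In all, edgeR called 860 genes at 72 h against air, 268 higher and 592 lower, of which 176 and 7 changed at least 2-fold. The split moved with the scaling: 224 higher and 282 lower with DESeq2 size factors, and 192 higher and 107 lower with upper quartile scaling. Leaving out the 2 libraries, 1126 genes were called, 701 higher and 425 lower, and 570 of the 860 were among them. All 860 kept their sign, but the fits share most libraries, so genes picked in the full fit tend to keep it. The count was 204, 35 and 31 without air replicate 1, 2 and 3, 301 and 1617 without replicate 1 and 2 at 24 h, and 59, 31 and 54 without replicate 1, 2 and 3 at 72 h. Of the 55 called genes that the rule for named genes takes, 5 were called with each of the 9 libraries left out in turn, Cldn18, Emp2, Gprc5a, Atf4 and Cxcr2. The number of the 55 called was 25, 9 and 5 without air replicate 1, 2 and 3, 30, 54 and 48 without replicate 1, 2 and 3 at 24 h, and 10, 6 and 9 without replicate 1, 2 and 3 at 72 h.

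**Figure D3:**
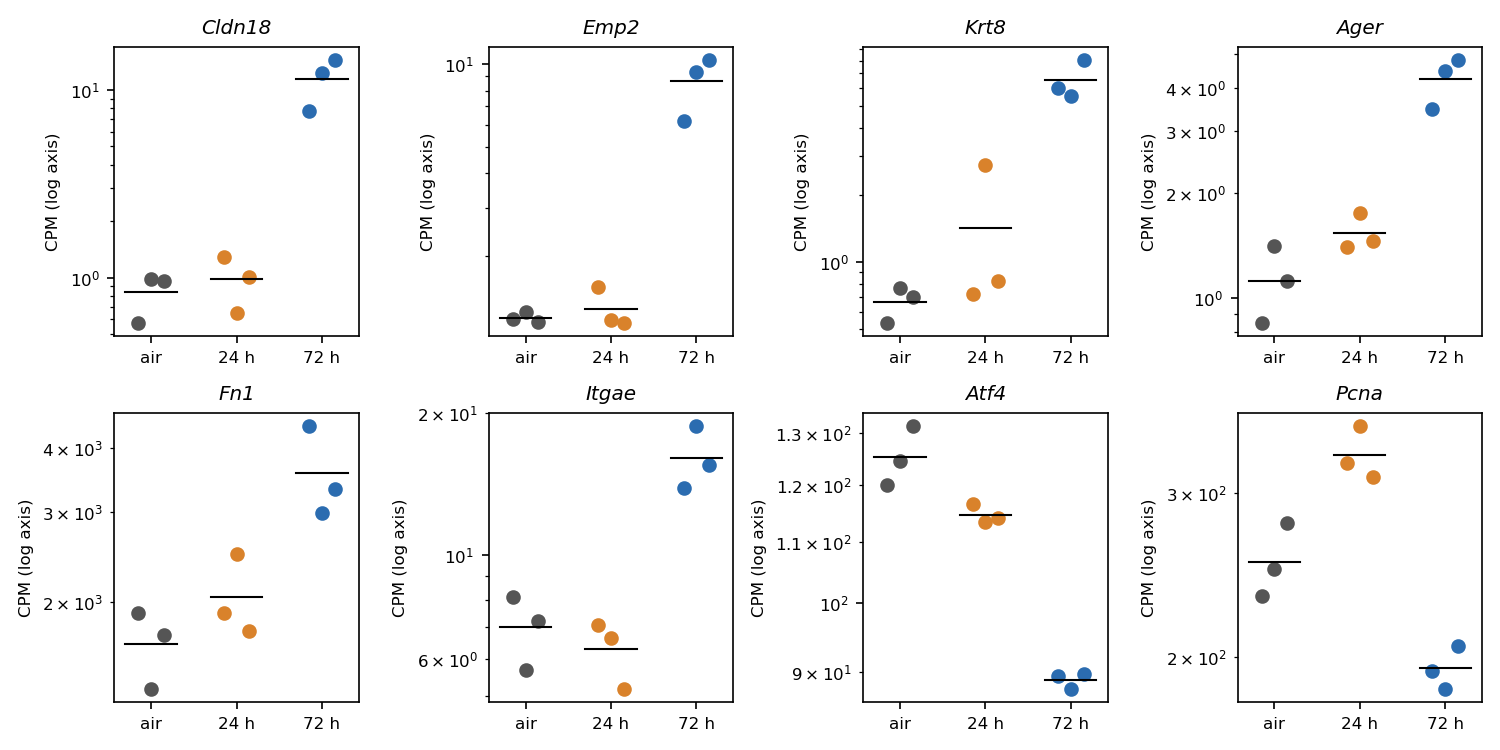
CPM (log axis) of 8 genes in the 3 groups; each point is 1 library and the line is the mean of 3. For Cldn18 the air and 24 h libraries lie between 0.571 and 1.28 CPM and the 72 h libraries between 7.76 and 14.4 CPM.

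The third comparison asked whether the response at 72 h differed from that at 24 h. Genes of DNA replication fell between the 2 times. Pcna (ENSMUSG00000027342.14, chromosome 2, 132249162 to 132253314) went from 329.7 ± 21.6 to 195 ± 10.5 CPM (-0.76 ± 0.09, edgeR adjusted p = 0.00406), Uhrf1 from 86.5 ± 7.33 to 43.7 ± 3.50 CPM (-0.99 ± 0.15), and the helicase subunit Mcm3 from 145 ± 9.70 to 83.9 ± 5.86 CPM (-0.79 ± 0.10). Of 21 genes of DNA replication, 19 were lower, 2 were not called and 21 were lower adjusted over the list alone. Of 22 genes of G2 and mitosis, 16 and 20, among them Cdk1 (-0.82 ± 0.14), Tpx2 (-0.58 ± 0.08) and Top2a (196 ± 5.63 to 124 ± 9.49 CPM). Dut, an enzyme of nucleotide supply, fell by 1.09 on the log2 scale. Camera gave adjusted p = 4.4e-13 and 3.49e-08, adjusted p = 0.528 for both with an estimated correlation, and fry 0.00606 and 0.0192 (0.0424 and 0.0639 without the 2 libraries). With the 2 libraries left out, 19 and 15 members were lower.

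Of the oxidative phosphorylation, cholesterol and tricarboxylic acid cycle lists most genes fell over the same interval. Of 23 oxidative phosphorylation genes, 21 were lower and 23 adjusted over the list alone, among them Cycs (-0.47 ± 0.07) and Ndufa4 (-0.45 ± 0.07). Of 20 cholesterol genes, 16 were lower (19 adjusted over the list alone); Idi1 (ENSMUSG00000058258.14, chromosome 13, 8885501 to 8892451) went from 128 ± 16.6 to 69.7 ± 7.96 CPM (-0.87 ± 0.15) and Fdps from 102 ± 11.1 to 52.0 ± 6.91 CPM (-0.97 ± 0.17). The tricarboxylic acid cycle had 9 of 16 lower (12 adjusted over the list alone), glycolysis 8 of 19 (8) with Pgk1 at -0.54 ± 0.08, and fatty acid oxidation 4 of 18 (6). The numbers lower without the 2 libraries were 13 for oxidative phosphorylation, 19 for cholesterol, 2 for the tricarboxylic acid cycle, 6 for glycolysis and 1 for fatty acid oxidation. In order, the camera adjusted p was 4.61e-11, 9.1e-08, 2.01e-05, 0.00258 and 0.0319, and with an estimated correlation the adjusted p = 0.528, 0.541, 0.528, 0.528 and 0.841. Fry gave 0.00518, 0.0279, 0.00626, 0.00626 and 0.120, and without the 2 libraries 0.0424, 0.0444, 0.0449, 0.0573 and 0.133. The fatty acid oxidation call ended without replicate 1 (adjusted p = 0.177) or 3 (0.0562) at 24 h, without replicate 1 at 72 h (0.261) and without both libraries carrying B cell markers (0.0903). Of 17 stress response genes, 7 were lower (8 adjusted over the list alone), Sdf2l1 (-0.60 ± 0.06), Manf (-0.62 ± 0.07) and Atf4 (-0.37 ± 0.05) among them (9 without the 2 libraries), with camera adjusted p = 2.7e-05, adjusted p = 0.528 with an estimated correlation, and fry 0.00448.

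Of the repair, dendritic cell and epithelial lists, 6 of 22, 4 of 14 and 6 of 18 genes rose from 24 h to 72 h. Igf1, a growth factor, rose from 13.7 ± 0.624 to 25.1 ± 1.93 CPM (0.88 ± 0.10, adjusted p = 0.00433), Mmp14 from 2.12 ± 0.652 to 6.77 ± 2.17 CPM and Fn1 from 2043 ± 388 to 3571 ± 741 CPM. The count for the repair list was the same adjusted over the list alone (camera adjusted p = 0.00350, adjusted p = 0.528 with an estimated correlation, fry 0.00626). Cldn18 rose by 3.55 ± 0.35, Emp2 by 2.75 ± 0.22 and Gprc5a by 2.74 ± 0.21, and 6 of 18 epithelial markers were higher, over all genes and adjusted over the list alone (adjusted p = 0.0343, 0.528 with an estimated correlation, fry 0.0186). The epithelial list's call ended without air replicate 3 (adjusted p = 0.0559), replicate 2 (0.0694) or 3 (0.0562) at 24 h, and without both libraries carrying B cell markers (0.117), with a median of 0.37 in all 9 libraries and 0.50 without the 2. Among 14 dendritic cell genes 4 were higher, Itgae at 1.35 ± 0.18 and Flt3 at 1.30 ± 0.30 among them, and Batf3 was lower (-0.71 ± 0.17); camera gave adjusted p = 0.00880, 0.528 with an estimated correlation, and 0.0562 without replicate 3 at 24 h, and fry 0.0709. Leaving out the 2 libraries, 8 repair, 8 dendritic cell and 6 epithelial genes were higher and 1 of each list lower, and the dendritic cell median was 1.00 in place of 0.32. Il12b, a cytokine subunit, rose by 1.65 ± 0.43 and the cholesterol exporter Abca1 by 0.69 ± 0.19, whereas the chemokine Cxcl10 fell from 2.24 ± 0.452 to 0.899 ± 0.101 CPM (-1.32 ± 0.23). With each library left out in turn, Igf1, Mmp14, Itgae, Cldn18, Emp2 and Gprc5a were called in 9 of 9 fits, Cxcl10 in 8, Flt3 and Batf3 in 6, Fn1 in 4, Il12b in 3 and Abca1 in 1.

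Not called between the 2 times, with the median log2 fold change and camera adjusted p of each, were lipid handling (0.16, 0.0873), pro-inflammatory mediators (-0.03, 0.748), alternative activation (0.10, 0.533), NRF2 targets (-0.11, 0.106), interferon response (-0.24, 0.512), MHC class II (-0.09, 0.910), lysosome (0.05, 0.251), pattern recognition receptors (0.11, 0.120), p53 targets (-0.12, 0.694), iron handling (-0.17, 0.484). Among cell type lists these were resident alveolar macrophages (0.04, 0.271), monocytes (-0.20, 0.273), interstitial macrophages (0.20, 0.192), neutrophils (-0.37, 0.694), T cells (-2.83, 0.694), B cells (-0.69, 0.694), natural killer cells (-1.27, 0.926), endothelium with fibroblasts (0.06, 0.130) and erythroid cells (-0.44, 0.402). Without the 2 libraries camera called 6 of these lists: endothelium with fibroblasts (3.46, adjusted p = 0.000372, 5 of 9 genes higher), interstitial macrophages (0.78, 0.000203), T cells (0.88, 0.0440) and pattern recognition receptors (0.22, 0.0332) higher, and B cells (-2.22, 0.00236) and erythroid cells (-3.25, 0.00636) lower. With an estimated correlation their adjusted p = 0.239, 0.557, 0.712, 0.574, 0.574 and 0.585. NRF2 targets had 4 genes lower, Prdx6 (-0.39 ± 0.07) among them, and 2 without the 2 libraries. Direction differed in sign from the median for pro-inflammatory mediators (mean 0.06, up), MHC class II (mean -0.04, up), monocytes (mean -0.18, up), neutrophils (mean -0.33, up) and natural killer cells (mean -1.24, up), and the mean alone for alternative activation (-0.14).

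In all, edgeR called 2855 genes between 72 h and 24 h, 847 higher and 2008 lower at 72 h, of which 259 and 35 changed at least 2-fold. With upper quartile scaling the split was 1163 higher and 1302 lower, and without the 2 libraries 1042 higher and 1364 lower (2406 genes, 1741 of them among the 2855). Of the 2008 genes lower at 72 h, 1785 had a fitted level above air at 24 h, 1722 lay above air at 24 h and below it at 72 h, and 470 were also called between 72 h and air. Of the 847 genes higher at 72 h, 814 lay above air at 72 h, 143 above air at 24 h, and 197 were also called between 72 h and air. Genes picked as differing between the times tend to lie on opposite sides of air by that choice alone, and no value for unchanged genes was computed. Camera called 11 of 30 lists, 3 higher and 8 lower; with an estimated correlation it called 0, with 2 at an unadjusted p under 0.05, and fry called 9. The count of genes was 1408 without replicate 1 at 24 h and 1767, 658 and 1404 without replicate 1, 2 and 3 at 72 h. Of 79 called named genes, 40 were called with each of the 9 libraries left out in turn, among them Pcna, Mcm3, Uhrf1, Cldn18, Igf1 and Atf4. The number of the 79 called was 73, 68 and 72 without air replicate 1, 2 and 3, 53, 65 and 63 without replicate 1, 2 and 3 at 24 h, and 60, 40 and 54 without replicate 1, 2 and 3 at 72 h.

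The changes at 24 h and 72 h against air were also compared with each other. H1f0 was lower at both times, -0.55 and -0.36, and was the 1 gene called lower at both, where independent lists of 1 and 592 among 15713 would share 0.0377. In the other direction 0 genes were called higher at both, since edgeR called 0 genes higher at 24 h (2314 genes in both directions at an unadjusted p under 0.05, and 422 higher by DESeq2). Without the 2 libraries 2 genes were higher at both times and 4 lower, with 0.714 and 0.216 for independent lists. These expectations for independent lists take no account of the shared air libraries, which raise such overlaps without any shared response. Across genes, which are not independent replicates, the log2 fold changes had Pearson's r = 0.621 and Spearman's rho = 0.239. Unchanged groups simulated against the same 3 simulated air libraries gave 0.496 and 0.455 over 100 simulations. Each gene was drawn independently there, so deviations that many genes share in a real air library are not included. The covariance was 0.205 against a simulated 0.0902, a difference of 0.114, and with 3 controls that cannot be split part of it may come from the shared controls. B cell and serous cavity transcripts lay in 1 library of each time: without those 2 libraries r was 0.265 and rho 0.0583, with simulated values of 0.3903 and 0.354 and covariances of 0.0553 and 0.0310, and without replicate 2 at 24 h or replicate 1 at 72 h alone r was 0.314 or 0.401. A test for any difference among the 3 groups called 2081 genes, 1750 without the 2 libraries (1139 of them among the 2081), 853 without air replicate 2, 563 without replicate 1 at 24 h, and 391, 30 and 324 without replicate 1, 2 and 3 at 72 h.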

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

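The tests of the alveolar and airway lists were chosen, and the reading of the other splits was written, only after the results were seen. A difference between the 2 times after ozone, tested directly by edgeR, marked the following results: 2855 genes differed between 72 h and 24 h. Camera called 11 lists between the times, with median log2 fold changes of -0.77 for DNA replication, -0.56 for G2 and mitosis, -0.27 for glycolysis, -0.33 for oxidative phosphorylation, -0.20 for the tricarboxylic acid cycle, -0.12 for fatty acid oxidation, -0.52 for cholesterol biosynthesis, 0.43 for tissue repair, -0.34 for the stress response, 0.32 for dendritic cell and 0.37 for lung epithelium genes. With an estimated correlation camera called 0 of them, with a smallest adjusted p of 0.528 and 2 lists at an unadjusted p under 0.05, and fry called 9.

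Of 74 genes that the rule names in a comparison with air, called there or on the roster, 38 also differed between the times. Over all genes, 2855 of 15713 (18.2%) did. The 72 h libraries enter both comparisons, so genes picked at 72 h against air tend to differ between the times by that choice alone. Higher at 72 h than at 24 h were H1f0 (0.20), Ptgs2 (1.83), Cldn18 (3.55), Krt8 (2.21), Krt18 (2.29), Gprc5a (2.74), Emp2 (2.75), Ndnf (2.41), Apol7d (1.21), Fn1 (0.81), Mmp8 (0.58), Mmp14 (1.68), Ace (0.36), Cxcr2 (0.69), Itgae (1.35), Zbtb46 (0.87), Flt3 (1.30), Ager (1.46) and Aqp5 (2.05), and lower were Atf5 (-0.73), Fabp1 (-0.66), Nutf2 (-1.42), Pcna (-0.76), Tpi1 (-0.42), Ldha (-0.43), Ndufa9 (-0.38), Ndufv1 (-0.40), Ndufs3 (-0.36), Cox6c (-0.29), Mdh2 (-0.44), Acadvl (-0.25), Etfb (-0.32), Hadh (-0.25), Gpx4 (-0.35), Txn1 (-0.34), Atf4 (-0.37), Manf (-0.62) and Creld2 (-0.58), each as the log2 fold change between the times.

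Other splits of the libraries were counted for each number of called genes. For 24 h against air 1 gene was called and at most 1 in another split, and 2 of the 10 splits of the 6 libraries gave as many; for 72 h against air 860 against at most 1, and for 72 h against 24 h 2855 against 0, with 1 of 10 splits as large each time. These 10 splits are too few for a share under 0.05. Of 100 splits of the 9 libraries into 3 groups, only the real one, 1 of 100, reached 2081 genes for any difference. The highest of the others, 456 genes, kept the 72 h group whole. The 100 were a part of all such splits, so chance is unlikely for this count but not excluded. The count cannot tell an effect of ozone from another difference of the 72 h mice, such as colony or litter.

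The epithelial genes that rose at 72 h could come from epithelial cells in the lavage or from the macrophages. Airway markers as a group did not rise with them. The 5 under 5 CPM in air, 4 of them also in the lung epithelium list (Scgb3a1, Scgb3a2, Foxj1 and Muc5b), had a median log2 fold change of -0.048. None exceeded 0.53, and the median over all 9 tested airway markers was -0.20. The lowest of 6 called lung epithelium markers was 1.35, but these 6 were picked by their change, so that gap is no evidence. So few genes of low level cannot exclude airway cells. Alveolar epithelial cells are a candidate source that stays open. Of 14 alveolar markers under 5 CPM in air, 13 lay above air at 72 h, and 5 were also lung epithelium markers of the report. The 14 had a median of 1.09, at percentile 99.8 of 10000 random lists matched on expression. The 9 outside the lung epithelium list, of which Col4a3, Cxcl15 and Muc1 were called, had a median of 0.87 at percentile 97.2. The random lists were matched on the mean of all 9 libraries and not held under 5 CPM in air, which can raise both percentiles. Over all levels the median was 0.58 for 10 type 1 and 0.66 for 10 type 2 markers. The summed levels of these 2 lists were 262.2 and 226.1 CPM in air and 261.5 and 245.5 CPM at 72 h. The abundant type 2 cell transcript Sftpc was 5.64 ± 1.76 CPM in air and 8.61 ± 1.75 CPM at 72 h (0.61 ± 0.30, edgeR adjusted p = 0.241), and Ager of type 1 cells 4.24 ± 0.692 CPM, both below Cldn18 at 11.5 ± 3.40 CPM. Expression of these genes by the macrophages themselves was not tested, since bulk RNA does not separate cells.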

How the results depend on the processing

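The tests chosen only after the results were seen were those without the 2 libraries carrying serous cavity markers, without these and the air library lacking Xist, and with the serous cavity level as a covariate. Among named genes, 5315 comparisons kept direction and side of the threshold, 824 lost the call, 36 gained one, 189 moved and 0 reversed; among lists 1247 were kept, 152 lost, 47 gained, 76 moved and 8 reversed. A gene or list called in neither fit counts as kept, so these sums overstate how often a call was kept. For each changed result below, the cause was not tested.

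For 24 h against air (1 gene), 1 other gene was called without the 3 libraries, 0 were called with no filter, with only the 6 libraries compared or with a 2-fold threshold of edgeR (2314 with all genes at an unadjusted p under 0.05), 618 by DESeq2, 24 without the 2 libraries, 5 with the covariate, and 0 to 2 with 1 library left out. For 72 h against air (860 genes), 506 were called with DESeq2 size factors, 299 with upper quartile scaling, 270 with no filter, 459 with 1 CPM in 3 libraries, 1936 by DESeq2, 1362 with only the 6 libraries, 183 with a 2-fold threshold, 430 without the 3 libraries, 1437 with the covariate, and 31 to 1617 with 1 library left out. For 72 h against 24 h (2855 genes), the counts were 1696 with no filter, 1885 with only the 6 libraries, 294 with a 2-fold threshold, 1846 without the 3 libraries, 4350 with the covariate, and 658 to 2776 with 1 library left out. For any difference (2081 genes), they were 1167 with no filter, 3689 by DESeq2, 882 without the 3 libraries, 3503 with the covariate, and 30 to 2242 with 1 library left out.

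Lists called at 24 h (18) numbered 11 without the 2 libraries, 9 without the 3, 0 with an estimated correlation, 2 by fry, and 8 to 20 with 1 library left out; at 72 h (15) 0 with an estimated correlation, 8 by fry, and 9 to 17; between the times (11) 0 with an estimated correlation, and 9 to 15. The correlation of the responses (0.621) was 0.265 without the 2 libraries and 0.314 to 0.689 with 1 left out. Medians that reversed among the lists called at 24 h were -0.039 for interferon response (0.036 to 1.06 with 1 library left out), 0.0068 for lysosome and -0.30 for T cells without the 3 libraries, and 0.010 for lysosome without replicate 2 at 24 h or without the 2 libraries (-0.13 at the lowest with 1 left out). At 72 h against air the B cell median, 0.31, had the opposite camera direction with the covariate, and between the times the T cell median was 2.43 without replicate 2 at 24 h (-4.17 without replicate 1 at 72 h), 0.88 without the 2 libraries and 0.86 without the 3.

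With the replicate number as a block, 0 genes were called at 24 h, 35 at 72 h against air, 1474 between the times and 106 for any difference. The labels do not say that a number marks anything shared. Deviations of samples with the same number correlated between -0.613 and 0.475. Replicate 2 at 24 h and replicate 1 at 72 h, which carried serous cavity markers, correlated at 0.731 with different numbers. These 2 libraries weigh heavily on the other correlations, so the check cannot tell whether a number marks something shared. Depth of 47095543 to 60248305 counts left 15713 of 54281 genes testable.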

Other observations

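All tests in this part were chosen only after the results were seen, and so were the genes. Without the 2 libraries carrying serous cavity markers, 24 genes were called between 24 h and air, and 1, which was not H1f0, when the air library lacking Xist was left out as well. Fasn, the fatty acid synthase, was 102 ± 8.49 CPM in air and 180.3 and 168 CPM in the remaining 24 h libraries (log2 fold change 0.77 ± 0.08, edgeR adjusted p = 0.0237). Also higher were Lss of sterol synthesis (0.64), the glucose transporter Slc2a1 (0.61), Cad of pyrimidine synthesis (0.46), the chromatin assembly factor Chaf1a (0.61), Spp1 (0.69), Slfn9 (0.72) and the chemokine Cxcl10 (1.80). Lower were the antiprotease Slpi (-0.65), the cold-inducible RNA-binding protein Cirbp (-0.70), the glutathione transferases Mgst1 (-0.43) and Mgst2 (-1.03), and H1f0 (-0.57). With all 9 libraries, H1f0 alone of these was called.

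Some genes outside the fixed lists rose from under 1 CPM at 72 h. The laminin chain Lama5 reached 3.60 ± 0.466 CPM from 0.353 ± 0.0198 CPM (3.34 ± 0.18, edgeR adjusted p = 0.000544). Clic5 rose by 3.73 ± 0.29, the keratin Krt7 by 2.65 ± 0.24, the integrin Itgb6 by 2.97 ± 0.48 and the claudin Cldn4 by 2.97 ± 0.51. From higher levels, the chemokine Cxcl16 rose from 11.5 ± 1.80 to 21.6 ± 3.92 CPM (0.91 ± 0.17), whereas the folate enzyme Mthfd2 fell from 29.9 ± 2.67 to 19.6 ± 0.782 CPM (-0.61 ± 0.08). Trib3, a target of Atf4 and itself a member of the fixed stress response list, fell by 0.88 on the log2 scale.

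Replicate 2 at 24 h and replicate 1 at 72 h held 784 and 1019 CPM of serous cavity macrophage markers, 1500 and 73.1 CPM of thymocyte markers, and all 14 B cell markers above the other 7 libraries. For serous cavity and B cell markers the values argue against a response of this size shared by the mice of a group. The highest serous cavity level among the other 4 ozone libraries was 8.61 CPM, against 7.54 CPM in air. B cell markers, a list fixed in advance, reached 14.9 CPM there and 4.87 CPM in air. Red cell markers reached 874 CPM in replicate 1 at 24 h, against 94.9 CPM in air. Without the 2 libraries camera called B cell, neutrophil and red cell markers higher at 24 h, but not with an estimated correlation. A smaller shared rise therefore stays open. Cells other than lung macrophages, collected with these 2 samples, are a candidate explanation: resident macrophage markers lay lower there than in the other libraries of their group, with a median log2 difference of -0.39 over 20 genes, 19 of them lower (percentile 0.01 of 10000 matched lists), in replicate 2 at 24 h, and -0.18, with 17 lower (percentile 1.94), in replicate 1 at 72 h. The most abundant of the markers, Prg4 and Alox15, reached 317 and 151 CPM in the first and 402 and 251 CPM in the second. No sort that would remove such cells is given in the sources used here, and a response of single animals stays open.

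Xist, the RNA that silences an X chromosome in females, was 2.42 CPM in air replicate 2 and 887 to 1482 CPM in the other 8 libraries. The values argue against a male mouse, since Ddx3y, Eif2s3y and Uty had 0 counts there; Kdm5d, also Y-linked, had 8, within the 3 to 12 of all 9 libraries. Loss of Xist with both X chromosomes expressed is argued against too: X genes at 5 CPM or more, 307 of them, differed from 9716 autosomal genes by a median log2 of 0.0012. A single X chromosome in these cells may explain it: 6 X genes that escape inactivation had a median log2 difference of -0.52 from the other 8 libraries, below all 10000 matched lists (percentile 0), and 5 of them, such as Kdm6a (36.4 CPM against 58.6 to 74.8), were lower than in any other library. The number of chromosomes was not measured.

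The processed pseudogenes Gm2223, Rab11b-ps2 and Gm6158 were present or absent by group. Gm2223 (chromosome X, 33505661 to 33507010) had 183 to 208 counts and Rab11b-ps2 (chromosome 19, 7398424 to 7399077) 67 to 127 counts in the 72 h libraries, with 0 elsewhere, and Gm6158 (chromosome 14, 24069734 to 24070637) had 0 counts at 72 h and 297 to 807 elsewhere. A difference in colony or litter between the 72 h mice and the others is not given in the sources used here and was not tested, and it would be confounded with every comparison of the 72 h group.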
